A study of Drosophila melanogaster with 8 samples.

How the data were processed

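The samples were 8 whole-body RNA samples of Drosophila melanogaster, 4 of the dark-cd4 mutant and 4 of w1118, grouped by the genotype in the labels. Per the labels, flies were kept at 25 °C and 60% humidity with 12 h of light and 12 h of darkness, and 50 ng of RNA from each sample was amplified and labelled with Cy3. Per the file headers, the authors' spot values are intensity values on a linear scale from Agilent Feature Extraction 10.7.3.1, where the processed signal is already background-subtracted and detrended and is not normalized between arrays. The flags per spot, other 0 or 1 values in the deposited files, mark spots well above background, saturated spots and outliers. The deposited table of the whole series holds log2 values; set against the scanner files, each column followed the log2 processed signal minus the array's 75th percentile, centred on the probe's median over the 8 arrays, with r = 1 and a slope of 1 over 24647 probes (across probes, which are not independent). Its column medians were -0.041, -0.012, 0.009 and -0.012 for control 1 to 4 and 0.053, 0.028, -0.015 and 0.034 for mutant 1 to 4. The authors' software and any threshold behind that table are not given in the sources used here. All 8 arrays share 1 slide and 1 scan, so slide and scan cannot differ between groups; the slide has 2 rows that each hold both genotypes, while each column position holds 1 genotype, so column position and genotype cannot be told apart.

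Each array has 62976 spots, of which 61657 are not control spots and belong to 32242 probes. By their names, 80 of these probes are meant for added bacterial RNAs, and they were left out. Outlier spots were left out, spots of one probe were averaged on the log2 scale, and no spot was saturated. The main values were log2 of the processed signal minus each array's 75th percentile of it. Probes well above background on at least 4 of the 8 arrays entered, 24647 in all, and each target was represented by its probe with the highest mean over all arrays, which left 19204 targets. A target is a gene symbol where one could be given, and otherwise the array's own identifier, so several targets can be transcripts of 1 gene. Choosing the brightest probe favours probes that kept their signal. The agreement of probes was therefore tested with every probe that entered fitted separately, each target counted once by its most changed probe in the given direction. That choice favours low ratios of the other probes to it.

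Gene names came from a reference table of the Release 6 assembly. Of 32162 fly probes, 384 were named: 219 by accession, 19 by symbol or synonym and 146 by the name of a cDNA clone. Another 31777 had no match and 1 matched several genes; 20979 carry FlyBase transcript numbers. The named probes cover 324 genes, of which 266 were tested, 99 of them through a clone name, and CG8204, CG11841, LysE and obst-B are named in this way. The array's grid names another build (dm3), so no coordinates are printed, and the reference served only for names and for which genes lie near dark. This departs from the plan, which took positions from the array files or from a table of the same build.

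Genotypes were compared with limma 3.58.1 (lmFit and eBayes with a variance trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; Python 3.11.15 and matplotlib 3.10.9 were also used. Gene lists were tested with camera with a preset correlation of 0.01, adjusted over the 5 lists with at least 2 tested members. Of 28 lists fixed before the data were examined, 21 had 0 tested members: apoptosis machinery, antimicrobial peptides, Bomanins, Toll, Imd, JAK/STAT and JNK pathways, methionine and one-carbon metabolism, insulin and FOXO-linked genes, heat shock proteins, glutathione S-transferases, antioxidant enzymes, autophagy, hemocyte, ovary, testis, muscle, eye and nervous system markers, lipid storage and the circadian clock. Single values of 4 against 4 arrays were compared with two-sided exact permutation tests, and the window around dark with Fisher's exact test. The genes named were fixed by rule before the data were examined: dark and white, up to 10 rises and 10 falls of the largest size among called genes with a symbol whose groups did not overlap, up to 4 called members of each list or the member with the smallest p, and Gnmt and Sardh. The rule yielded 4 rises and 3 falls. Jon65Aiii, roX1 and the small structured RNAs were named after their values were seen. So were Idgf1, Mthfs, retn, CR33942, Vha100-3 and the 4 transcripts without a gene symbol.

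The procedure was tested on simulated data made from the real means and spreads of the 19204 targets, with 200 changed in the comparison of mutant and control. It recovered 54% of targets changed by 1 on the log2 scale, 87.5% at 2 and 96.5% at 3, with 4, 5 and 13 false calls, and made 0 calls with no change. The simulation holds no structure shared between arrays. Alternatives fixed before the data were examined covered background correction, normalization, centring, the authors' values, the filter, the probe rule, the replicate number as a block, array weights, the variance prior, outlier spots, other tests and leaving out each array. The row of the slide, the level of small structured RNAs as a covariate, leaving out 3 arrays and leaving out genes named through a clone were added after seeing the data. The files hold no mean signal column, so the normexp correction (offset 50) used the median signal.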

Results

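Whole adult flies of 2 genotypes were compared by 1-colour microarray: flies carrying the dark-cd4 allele in the w1118 background, and w1118 flies as the control. The gene dark encodes the fly counterpart of Apaf-1, the adaptor that activates the initiator caspase Dronc, and per the series title the mutant is deficient in apoptosis. The comparison asks which transcripts differ in adult flies with this mutation. Each genotype had 4 samples, each of total RNA from 5 flies at day 5 of adult life, and the mutant had been backcrossed for 6 generations to the control strain. The labels do not give the sex of the flies, nor say whether the samples came from separate cultures, so p-values measure only the spread between these samples. Between 70.3% and 78.0% of the non-control spots were well above background on each array. The 75th percentile of the processed signal was 492.6 ± 42.4 in control and 376.5 ± 107.3 in mutant arrays (mean ± SD, n = 4 each; two-sided exact permutation p = 0.114). The number of arrays limits the precision of each value below.

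The mutated gene could not serve as a check of the labels, because no probe could be matched to dark. The same held for white, the gene behind the control strain's eye colour, and for the sarcosine enzymes Gnmt and Sardh. Most array targets carry FlyBase transcript numbers that the reference table used here does not pair with genes. A named gene was therefore available for 266 of the 19204 targets tested, and the accounts of named genes below cover that part of the array only.

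The gene CG6484 showed the largest rise among named genes. It was not well above background on any of the 4 control arrays and was well above it on all 4 mutant arrays, at least 430.4-fold higher in the mutant (limma, adjusted p = 1.12e-06). This bound sets the mean of the bright group against the mean, per array, of the higher of the dim probe's own signal and the lowest signal among probes well above background. CG12224 was likewise above background on the 4 mutant arrays and on 0 control arrays, at least 4.34-fold higher (limma, adjusted p = 0.00150). Both bounds hold for the processed signal only: with normexp correction of the median signal (offset 50) and quantile normalization, the differences were 4.11 and 0.23 on the log2 scale (limma, adjusted p = 8.77e-05 and 0.0196), again against control signals near background. In row 2 of the slide alone CG12224 was not called (limma, adjusted p = 0.0549). CG8204 rose by 1.63 ± 0.22 on the log2 scale (SE, n = 4 per genotype; limma, adjusted p = 0.00784), and CG11841 by 0.78 ± 0.13 (limma, adjusted p = 0.0214). The lysozyme genes LysB and LysE, which encode digestive enzymes of the gut, differed by -2.47 ± 0.25 and -2.22 ± 0.21 on the log2 scale (SE, n = 4 per genotype), and were thus 5.53-fold and 4.67-fold lower in the mutant, with limma adjusted p values of 0.00163 and 0.00127. LysB and LysE are near-identical neighbouring copies, so a probe for one can read the other and the assignment to each is uncertain. CG6484, CG12224, LysB and LysE each had 1 probe that passed the background filter. For them a sequence difference under the probe cannot be told apart from a change in RNA level. Os-C fell by 0.70 ± 0.12 (limma, adjusted p = 0.0260). For each of these 7 genes all mutant values lay on one side of all control values, which the naming rule required. The calls of Os-C and CG11841, the smallest changes of the 7, were also lost in several settings. With normexp correction and quantile normalization Os-C was at -0.43 (limma, adjusted p = 0.0540), and in rows 1 and 2 of the slide alone at -0.58 and -0.81 (limma, adjusted p = 0.0805 and 0.109); CG11841 was at 0.63 in row 1 alone (limma, adjusted p = 0.0671). With 1 array fewer, Os-C kept its size, at -0.73 to -0.68, but had adjusted p between 0.0692 and 0.0999 (limma) without any one of control replicates 1, 2, 3 and 4 or mutant replicate 2, and CG11841, at 0.71 to 0.80, had adjusted p between 0.0611 and 0.0822 without any one of control replicates 3 and 4 or mutant replicates 1 and 2.

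**Figure D1:**
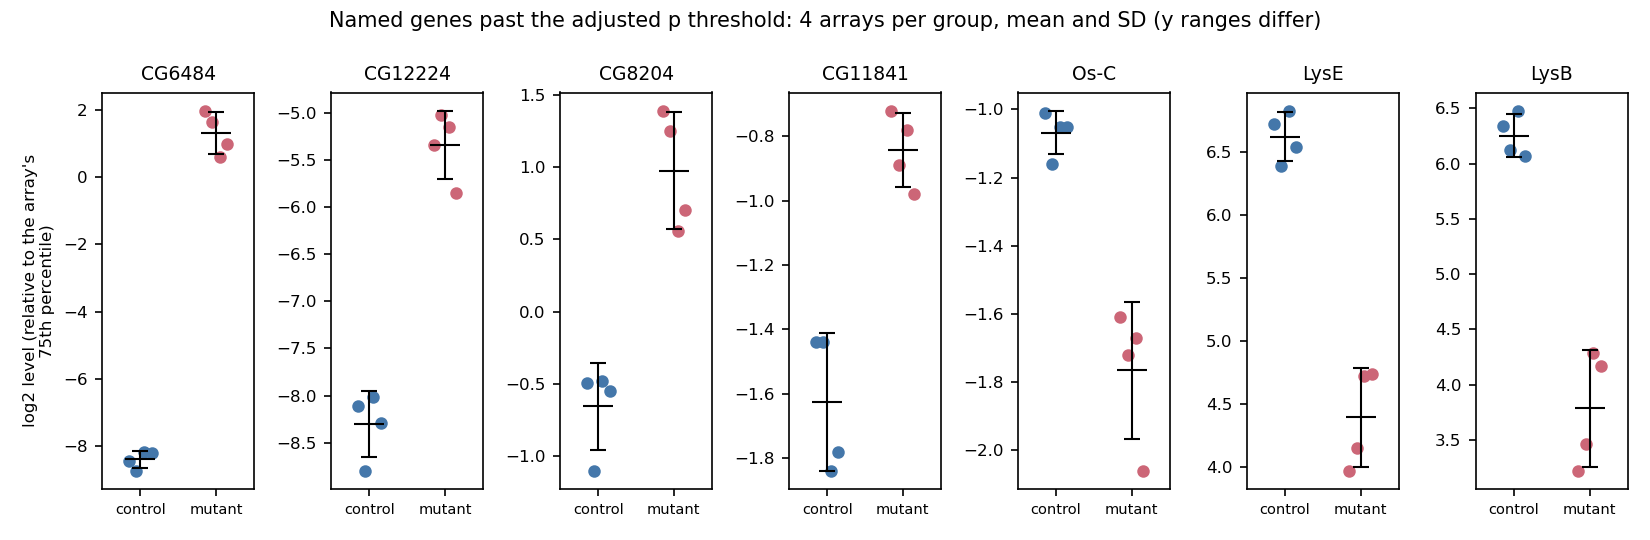
Log2 level of the 7 named genes past the adjusted p threshold on each of the 4 control and 4 mutant arrays, relative to the array's 75th percentile; points are arrays, bars the mean and SD of each group, and the y range differs between panels. CG6484 lies at -8.39 on average in control and 1.30 in mutant arrays, and LysB at 6.25 and 3.78.

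Among all 19204 targets, 420 differed between the genotypes (limma, adjusted p under 0.05), 246 higher and 174 lower in the mutant, and 4055 had an unadjusted p under 0.05. The change was at least 2-fold for 263 targets, 172 higher and 91 lower, and at least 4-fold for 113. Some targets were detected in 1 genotype alone: 17 of those called were well above background on all 4 mutant and 0 control arrays, and 16 on all 4 control and 0 mutant arrays. The transcript listed as FBtr0082504 was at least 263.6-fold higher in the mutant, and FBtr0087277 was higher, being well above background on 4 of 4 mutant and 1 of 4 control arrays, so no size is given for it. FBtr0086294 was at least 240.2-fold lower in the mutant and FBtr0086821 at least 60.5-fold lower. These 4 have limma adjusted p values between 1.12e-06 and 2.23e-05. Like those of CG6484 and CG12224, the fold bounds given for these transcripts hold for the processed signal only. The values of the mutant and control groups did not overlap for 2267 targets (11.8%), where chance gives 2.86% on average. Targets vary together between arrays, so the share by chance can differ from split to split. It was not counted for other splits, so the excess was not tested. The number of calls depended on the arrays used. It was 251, 172, 136 and 180 without control replicates 1, 2, 3 and 4, and 196, 153, 2528 and 282 without mutant replicates 1, 2, 3 and 4; the 2528 were 1227 higher and 1301 lower, so the larger share of higher calls did not hold there. All arrays lay on 1 slide, in 2 rows that each held 2 arrays of each genotype; the count was 1742 with the row as a block (829 higher, 913 lower), 910 in row 1 alone and 201 in row 2 alone. At least 2-fold, the corresponding counts were 513, 634 and 171. The main axis of variation between arrays (first principal component, 58.2% of the variance) did not separate the genotypes (two-sided exact permutation p = 0.0571). Its scores were 0.60, 0.52, -0.13 and 0.04 for mutant 1 to 4 and -0.01, -0.35, -0.36 and -0.32 for control 1 to 4. Mutant 3 correlated at 0.977 to 0.987 with the controls, at 0.965 and 0.969 with mutant 1 and 2, and at 0.990 with mutant 4.

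The gut digestive enzymes were the one called set among the 5 gene lists that had at least 2 tested members, lower in the mutant with the preset correlation (camera, adjusted p = 1.00e-04) and not called with an estimated correlation (camera, adjusted p = 0.127). Of the 49 members fixed, 3 could be tested: LysB and LysE fell, and the midgut protease Jon65Aiii differed by -0.52 ± 0.18 (SE; limma, adjusted p = 0.163 over all targets). Adjusted over the list alone, 3 of 3 passed. Of its 3 members 2 are the near-identical lysozymes, each with 1 probe that passed the background filter. With the preset correlation the set was also lower with the row of the slide as a block (camera, adjusted p = 3.29e-04), in row 1 alone (0.00750) and in row 2 alone (1.40e-05).

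No member passed in any other list with a tested member. The cytoplasmic ribosomal proteins, 3 tested, had a mean difference of 0.41 on the log2 scale (camera, adjusted p = 0.295), with RpS18 at 0.52 ± 0.28 (SE; limma, adjusted p = 0.310), 0.25 with the small structured RNA level described below as a covariate, 0.66 with array weights, 0.92 and 0.11 in rows 1 and 2 of the slide alone and 0.31 to 0.72 leaving out 1 array. The 3 tested members of oxidative phosphorylation had a mean of 0.14 (camera, adjusted p = 0.786); RFeSP, the Rieske iron-sulfur protein of respiratory complex III, differed by 0.23 ± 0.22 (limma, adjusted p = 0.560). It was at 4.59, 4.83 and 4.61 on control 1, mutant 1 and mutant 2 and between 3.98 and 4.08 on the other arrays, and its difference was 0.02 with the covariate, 0.07 with quantile normalization, 0.37 with array weights, 0.41 and 0.05 in rows 1 and 2 alone and 0.09 to 0.37 leaving out 1 array. The 2 cuticle and chitin genes had a mean of 0.01 (camera, adjusted p = 0.901), with the chitin-binding gene obst-B at 0.02 ± 0.15 (limma, adjusted p = 0.953), a value whose sign changes under other settings. The lone cytochrome P450 tested, Cyp4d20, differed by -0.10 ± 0.13 (limma, adjusted p = 0.673), and by -0.16 to -0.03 leaving out 1 array.

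Transcripts made in males were well above background on all 8 arrays. The roX RNAs, which coat the male X chromosome in dosage compensation, were at -0.13 ± 0.17 for roX1 and 0.73 ± 0.53 for roX2 (log2 difference ± SE; limma, adjusted p = 0.668 and 0.446), and camera gave the pair an adjusted p of 0.901. A second roX2 probe gave 0.33 ± 0.25. The level of roX2 was 0.64, 1.34 and 1.04 on control 1, mutant 1 and mutant 2, the arrays with high small structured RNAs, and between -0.95 and -0.52 on the others; its difference was 0.15 with that level as a covariate, 1.14 with array weights, 1.35 and 0.11 in rows 1 and 2 alone and 0.37 to 1.09 leaving out 1 array. Dup99B, a peptide of the male ejaculatory duct, differed by 0.08 ± 0.30 (limma, adjusted p = 0.897), a sign that turns with quantile normalization. The lists of ovary, testis, muscle, eye, nervous system and hemocyte markers had 0 tested members.

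Small structured RNAs (spliceosomal snRNAs, snoRNAs, 7SL RNA and the RNA of RNase MRP) varied strongly between arrays. Their mean log2 level was 1.19 in control replicate 1, 1.92 in mutant replicate 1 and 1.44 in mutant replicate 2, and between -0.68 and -0.23 on the other 5 arrays. These 3 arrays all lay in row 1 of the slide. All 12 tested RNAs had those 3 arrays above the other 5, and 0 of them passed the test between genotypes (limma; the smallest adjusted p was 0.385, for snRNA:U11, at 0.90 ± 0.57). The mean level was -0.0793 ± 0.865 in control and 0.606 ± 1.27 in mutant arrays (mean ± SD, n = 4 each; two-sided exact permutation p = 0.343). With this level as a covariate, 1901 targets were called (914 higher, 987 lower), among them all 420, and without those 3 arrays 409 were called, of which 244 were among the 420.

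**Figure D2:**
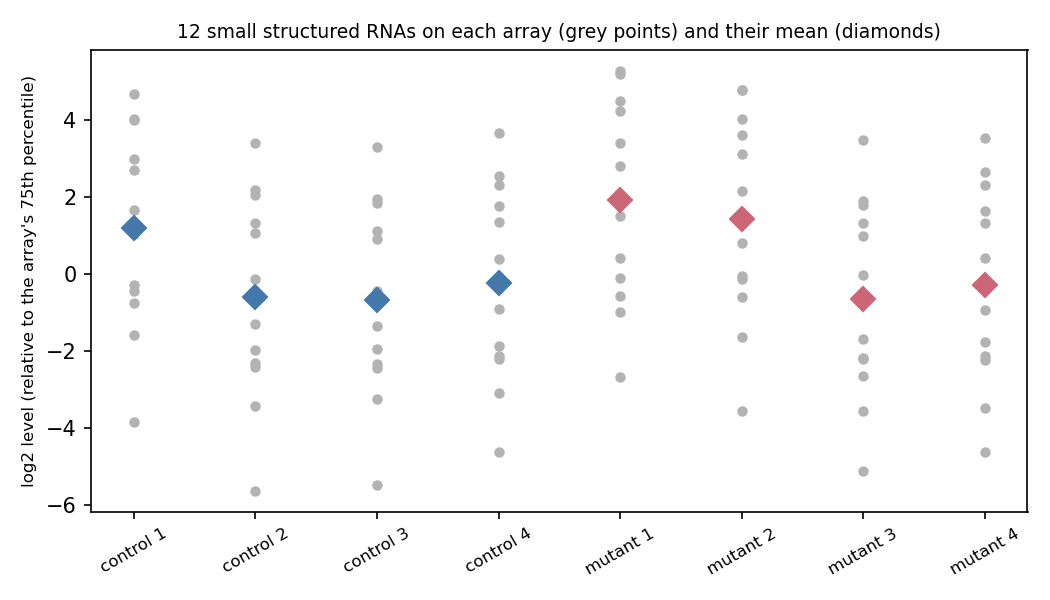
Log2 level of 12 small structured RNAs on each of the 8 arrays, relative to the array's 75th percentile; grey points are single RNAs and diamonds their mean on the array, blue for control and red for mutant. The means of control 1, mutant 1 and mutant 2 are 1.19 or above, and those of the other 5 arrays -0.23 or below.

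A backcross can leave sequence of the donor strain around the selected allele, so changed genes were counted near dark on chromosome arm 2R. Of the named genes within 5 Mb of dark, 2 of 22 were called, CG6484 and CG8204, against 5 of 244 elsewhere. The odds ratio was 4.73 (95% confidence interval 0.425 to 31.2; two-sided Fisher's exact p = 0.106), which does not pass the threshold. Within 2 Mb the counts were 2 of 11 and 5 of 255 (odds ratio 10.8, two-sided Fisher's exact p = 0.0292), and within 1 Mb 1 of 7 and 6 of 259 (odds ratio 6.90, two-sided Fisher's exact p = 0.172). Without genes named through a clone, CG8204 among them, 1 called gene remained within 5 Mb (odds ratio 5.58, two-sided Fisher's exact p = 0.221). With the row of the slide as a block in the fit the odds ratio within 5 Mb was 4.40 (two-sided Fisher's exact p = 0.00995), in row 1 alone 7.82 (p = 0.00109, exact) and in row 2 alone 12.4 (p = 0.00840, exact).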

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

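Of 30 groups of 4 arrays checked for a sample far from the others, 2 were flagged, about what chance gives at 1 in 20 groups. CG8204 was lower in control replicate 2, at -1.10 on the log2 scale, than in the other control arrays, which lay between -0.55 and -0.48. RFeSP was higher in control replicate 1, at 4.59, than in the other control arrays, between 3.98 and 4.08. Control replicate 1 is also 1 of the 3 arrays with high small structured RNAs.

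The tests in the next paragraphs, the counts over other splits included, were worded after the results were seen. The real split of the 8 arrays called 420 targets and 263 at least 2-fold, and was the only 1 of 35 splits with a count as large. The highest other split called 44 and 38. A share of 1 in 35 is the smallest that these splits can give, and it takes arrays of the 2 slide rows as interchangeable. The row as a block moved the count to 1742, so chance is not excluded by these splits. For the gut digestive enzymes the real split was also 1 of 35 with as small a camera p, with the smallest p of the other splits at 0.00124, but this uses the preset correlation, and with an estimated one the list did not pass (camera, adjusted p = 0.127). Only 18 splits keep 2 arrays of each group in each slide row, too few for a share under 0.05. Among these the real split was 1 of 18 for both counts and for the list; the other 17 called 0 targets, also with the row as a block, where the real split called 1742, and their smallest camera p was 0.00421.

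Small structured RNAs stood high together on control 1, mutant 1 and mutant 2. Genotype, the row of the slide and dim arrays each stay open. The mean level differed by 0.69 between mutant and control arrays (two-sided exact permutation p = 0.343) and by 1.45 between rows 1 and 2 (two-sided exact permutation p = 0.0857); all 3 high arrays lie in row 1, where control 2, at -0.60, is not high. For dim arrays, the level fell with the array's 75th percentile (Spearman rho = -0.74 and Pearson r = -0.77, exact permutation p = 0.0458 and 0.0202, 1 relation tested). The level is itself measured relative to that percentile, so a fall is partly built in and these p-values cannot decide the question. Without mutant 1 and mutant 2, the 2 arrays farthest from the median, r was -0.30. Both are among the 3 high arrays, so leaving them out removes most of the pattern and cannot decide it either. Differences in how well short RNAs were recovered may also play a part and were not tested. With the level as a covariate 420 of 420 calls were kept. Without the 3 high arrays, and so with fewer arrays, 244 of the 420 were called again. The level varied mostly within genotypes, so a target that follows it could hardly be called. The covariate fit therefore cannot decide whether the level accounts for the calls.

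Very large changes may reflect a sequence difference under a probe rather than a different RNA level. Where the target has another probe that passed the background filter, rises of at least 4-fold argue against a difference under 1 probe alone as a general cause. Over 17 such targets the other probes' change was 0.920 of that of the most changed probe in the median. Of these, 13 had a ratio of at least 0.5 and 4 had one under 0.25. Probes that failed the filter were not counted, which can favour agreement. Whether probes of 1 target overlap was not checked. A sequence difference that reaches all probes of a target would also leave them in agreement, and is not addressed by these ratios. Falls of at least 4-fold go the other way: over 7 such targets the median ratio was 0.0440, with 2 of at least 0.5 and 4 under 0.25, which is consistent with sequence differences or with transcript forms that differ between strains, and these were not told apart. Taking the most changed probe favours low ratios; with every such probe counted, several per target, the medians were 0.983 over 29 rises and 0.189 over 8 falls. No second probe passed the background filter for 98 of the 113 targets changed at least 4-fold. Among the 98 were CG6484, CG12224, LysB and LysE. The explanations cannot be told apart for these 98 targets. A true difference between the genotypes stays open for all of them.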

How the results depend on the processing

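The settings that use the row of the slide, the covariate, or leave out 3 arrays or clone-named genes, were chosen after seeing the data; no cause was tested for the shifts below. The normexp setting changes the signal column, the background correction and the normalization (to quantile) together. The 420 calls became 1047 with a replicate block, 2279 with array weights (1109 higher, 1170 lower; the weights stopped short of convergence), 1742 with the slide row as a block (829 higher, 913 lower), 910 and 201 in slide rows 1 and 2 alone, 1901 with the small RNA level as a covariate (914 higher, 987 lower) and 140 with a plain test per gene without pooled variance. The share of higher calls was 58.6%, and 48.7%, 47.6% and 48.1% with weights, row block and covariate. The 263 calls at least 2-fold became 161 in the normexp setting, 466 with the replicate block, 698 with array weights, 513 with the row block, 634 and 171 in rows 1 and 2 alone, 414 with the covariate and 80 with treat against a fold of 1.5. Leaving out 1 array gave 136 to 2528 calls and 118 to 752 at least 2-fold; without mutant replicate 3 the 2528 (1227 higher, 1301 lower) included all 420. The authors' values gave 413 calls, 412 of them shared.

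Nothing in the labels says that replicate numbers pair the samples, and pairing was not tested. Deviations of same-numbered arrays correlated at 0.68, -0.18, 0.29 and 0.33, and 4 of the 8 arrays correlated best with their own number. With the replicate number as a block the calls rose to 1047. Replicates 1 and 2 of both genotypes lay in row 1 of the slide and replicates 3 and 4 in row 2. The replicate block thus also takes up the row, which alone as a block gave 1742 calls. Neither the rise nor the correlations can tell pairing from the row. Pairing therefore stays open. A slide block was not run because there is 1 slide.

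The odds ratio near dark, 4.73, passed the threshold at 7.43 with quantile normalization, 5.14 with the replicate block, 5.17 with array weights, 10.8 within 2 Mb, 4.40 with the row block, 7.82 and 12.4 in rows 1 and 2 alone, 3.104 with the covariate and 7.43 without control 1, mutant 1 and mutant 2. Leaving out 1 array gave 3.58 to 7.90, and passed without mutant replicate 3 (3.58) and without mutant replicate 4 (7.43). With probes well above background on all 8 arrays it was 2.84 (two-sided Fisher's exact p = 0.354), and without clone-named genes 5.58 (two-sided Fisher's exact p = 0.221), with 1 called gene inside. Against genes of the same arm the counts were 2 of 22 and 0 of 26, with no finite odds ratio (two-sided Fisher's exact p = 0.205). The gut list's p of 2.01e-05 rose to 0.0254 with an estimated correlation (adjusted p = 0.127); leaving out 1 array gave 1.99e-06 to 4.75e-04.

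Of 310 values of named genes under alternatives, 283 kept direction and side of the threshold, 14 lost significance (Os-C in 8 settings, CG11841 in 5, CG12224 in row 2 alone) and 13 changed sign. Dup99B was -0.04 with normexp, -0.03 with quantile normalization, -0.16 in row 2 alone, -0.18 with the covariate and -0.18 without the 3 arrays, and -0.19 to 0.24 leaving out 1 array, negative only without control replicate 4 or mutant replicate 1. The value of obst-B was -0.00 in row 1 alone, -0.04 with the covariate and -0.06 to 0.12 leaving out 1 array, negative only without control replicate 2 or 4 or mutant replicate 1 or 3. Neither was called in any setting. The camera direction of uncalled lists, with the test value in brackets, turned for oxidative phosphorylation with normexp (0.837), quantile normalization (0.774), row 2 alone (0.868), the covariate (0.627) and without the 3 arrays (0.958), and for cuticle and chitin without a filter (0.924), in row 2 alone (0.574), with the covariate (0.426), and without the 3 arrays (0.766). Leaving out 1 array, the cuticle list turned without control replicate 2 (0.781), control replicate 4 (0.882) or mutant replicate 1 (0.672) and not in the other 5 cases, within a range of 0.436 to 0.921.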

Other observations

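The tests in this part were chosen after the data were seen. With the small RNA level as a covariate 26 of the 266 named genes were called, and with the row of the slide as a block 25. Of these, 16 passed in both, 9 higher and 7 lower in the mutant, including all 7 called without either term. Among all 19204 targets 1406 passed in both, so the named genes were not called more often than the array as a whole. Among the further genes, the imaginal disc growth factor gene Idgf1 differed by 1.55 ± 0.36 on the log2 scale with the covariate (SE; limma, adjusted p = 0.0289) and by 1.81 with the row block (limma, adjusted p = 0.0151), against an adjusted p of 0.0625 without either. Mthfs, an enzyme of folate metabolism, differed by 0.98 ± 0.20 and 1.29 (limma, adjusted p = 0.0180 and 0.0293; 0.0984 without either), and the transcription factor gene retn by 0.60 ± 0.13 and 0.69 (limma, adjusted p = 0.0252 and 0.0311; 0.0625 without either). The long noncoding RNA CR33942, which lies within 5 Mb of dark, differed by 1.57 ± 0.22 and 1.97 (limma, adjusted p = 0.00335 and 0.00110; 0.0507 without either). The V-ATPase subunit gene Vha100-3 was lower, at -0.43 ± 0.11 and -0.58 (limma, adjusted p = 0.0408 and 0.0330; 0.136 without either). Idgf1 was well above background on 3 of 4 control arrays, with a mean log2 level of -6.43 in control. The size of its change therefore rests on control signals near background.

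Sequence linked to dark and kept through the backcross is a candidate explanation for changed genes near it. The odds ratio within 5 Mb was 4.73, with an interval from 0.425 to 31.2, which rests on 2 called genes. It passed under several other settings, among them 4.40 with the row block (two-sided Fisher's exact p = 0.00995), 5.14 with the replicate block (exact p = 0.0204), 5.17 with array weights (exact p = 0.00302), 3.104 with the covariate (exact p = 0.0494), and 7.82 and 12.4 in rows 1 and 2 alone (exact p = 0.00109 and 0.00840). It did not pass in others. Among these were 2.84 with probes well above background on all 8 arrays (exact p = 0.354), 5.58 without clone-named genes (exact p = 0.221) and 6.90 within 1 Mb (exact p = 0.172). Also among them were 5.92 in the normexp setting (exact p = 0.0800), 4.73 with the authors' values (exact p = 0.106) and the test against genes of the same arm (exact p = 0.205). The same held for 6 of the 8 fits that leave out 1 array. CR33942 and Vha100-3, named above, lie within 2 Mb of dark. The planned test did not pass, and its interval is wide. The settings with the row or the covariate were added after the data were seen. Quantile normalization (odds ratio 7.43, two-sided Fisher's exact p = 0.0211) and the 2 Mb window (10.8, exact p = 0.0292) were planned and passed. So were the replicate block, array weights and the fits without mutant replicate 3 or 4. As other planned settings did not pass, the question is left open. The flies also differ in dark itself, so an effect of the mutation on its neighbours stays open too, as untested.

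Targets changed at least 2-fold were spread unevenly over FlyBase transcript numbers. In 43 ranges of 1000 numbers with at least 50 targets each, 186 of 13816 targets (1.35%) had changed; the highest shares were 21 of 526 (3.99%) from 87000 to 87999 and 17 of 447 (3.80%) from 86000 to 86999. A first test, of the highest share alone, did not pass (permutation p = 0.375 over 10000 permutations). A second test, tried after the first, took the chi-square over all ranges and gave permutation p = 1.00e-04, the smallest that these permutations can give. Neighbouring numbers can be transcripts of 1 gene, so the second test was repeated with runs of neighbouring numbers kept together, which gave permutation p = 0.0015. With 1 of 3 tests not passing and the form of the others chosen afterwards, the uneven spread is a hypothesis, and the numbers are not paired with places in the genome here.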
